A study of Mus musculus with 23 samples.

How the data were processed

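RNA of sorted cells from Met1-iRFP breast tumours in FVB mice was measured by sequencing of polyA RNA. Met-1 is a mouse mammary cancer line derived from a tumour of the MMTV-PyMT model, and iRFP is a near-infrared fluorescent protein that marks its cells. Per the labels, the iRFP-positive sort holds cancer cells and the iRFP-negative sort holds cells of the tumour microenvironment (TME), each from exercised or sedentary mice. The 23 libraries form 4 groups, with 8 libraries of sedentary and 7 of exercised cancer cells, and 4 libraries of TME cells in each treatment. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with the KAPA Standard mRNA-Seq kit. Per the submitters' processing notes, reads were aligned with STAR and counted with featureCounts on the mm10 build. Versions, the annotation release and the strand setting are not given in the sources used here.

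The authors deposited 1 table of raw read counts, with 48397 gene symbols and 23 columns, of which every column was used. The table holds 16422 symbols with no count in any library, no duplicated symbol and no unnamed entry. Gene coordinates are those of GRCm38 (mm10) in the GENCODE M21 annotation, matched by symbol for 46294 symbols, or 95.65% of the table. As no strand setting is stated, reads of overlapping and antisense genes cannot be told apart. Near-identical copies, such as the H2-Q, Gbp, tryptase and ribosomal protein genes with their pseudogenes, may share reads, and their values are uncertain for that reason.

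The counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr, libraries were scaled by TMM, and the robust quasi-likelihood test was applied, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Every adjusted p for a gene comes from this test unless another tool is named. The exercise effect was fitted on the 15 cancer libraries and, separately, on the 8 TME libraries. The difference between these effects and the contrast of cancer against TME cells were fitted on all 23 libraries in 4 groups. No covariate or block was used, since the labels give no batch and do not state that numbers pair mice. The labels do not state that each library is a separate animal, so p-values measure the spread between libraries. Fold changes are log2 values ± the standard error of the fit, and CPM values are TMM-scaled means ± SD over libraries.

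The comparisons, their tests, 68 gene lists of cell types and pathways, 72 ligand and receptor pairs, the genes always reported and most alternatives were chosen before the data were examined. Each list with at least 5 tested members was tested against all other genes with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. The level of a list in a library is the mean log2 CPM of its members with a prior count of 2. Levels were compared by two-sided exact permutation tests, planned for the cell type lists and extended to all lists after the data were seen. In cancer cells 6435 splits give a smallest p of 0.000155, and in TME cells 70 splits give a smallest p of 0.0286. The correlation of both exercise effects across genes was set against 100 permutations of the treatment labels.

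The genes named are the 5 with the smallest p in each direction where no gene passed the threshold, with predicted genes and receptor gene segments left out of the ranking, the genes always reported, and up to 4 members with the smallest p of each list described. For cancer against TME cells they are the 8 largest changes in each direction with a mean log2 CPM of at least 1. Tnfrsf25 and Il20rb in the mean of both effects, Spp1, Wfdc2 and the clock output genes were singled out after their values were seen. Of the genes always reported, 3 are counted in the totals and not reported here.

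The alternatives were DESeq2 1.42.0, limma voom with quality weights, RLE size factors, no filter, a mean CPM of at least 1, all libraries in 1 fit, the replicate number as a block, marker levels as covariates, 1 surrogate variable from sva 3.50.0, and each library left out in turn. Within a compartment the block rests on the numbers found in both treatments. These are 2, 4, 5, 7 and 10 in cancer cells and 9 and 10 in TME cells. The other libraries then carry no weight in the exercise effect. In the fits on all 23 libraries the block was the number within a treatment, and the 7 with both sorts carry the comparison. Length and GC correction by splines, removal of the exercised TME libraries 8 and 9, and the leukocyte covariate in TME cells were added after the data were seen. So were the gene lists in the difference between compartments and the mean of both effects.

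The gene test and the list test were tried on simulated data with the real means, dispersions and library sizes. The genes changed singly were drawn from those with a mean CPM of at least 1 and in no gene list, so the shares called do not cover rarer genes. Of 100 genes changed by a fold of 1.5, the test called 65% in cancer cells, 11% in TME cells, 15% in the difference and 76% in cancer against TME cells. At a fold of 2 these shares were 93%, 52%, 58% and 85%. False calls were 8 of 178, 3 of 67, 4 of 79 and 5 of 181 in the same order. A list shifted by 0.5 log2 was called in all 4 comparisons, with the preset and with the estimated correlation, and no other list was called. Correlation between genes is not among the features matched to the real data. The simulation therefore cannot show how often unchanged lists are called with the preset correlation in the real libraries. Other splits of the real libraries called up to 26 lists in cancer cells and up to 35 in TME cells.

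The libraries hold 15924340 to 37388479 counts. At this depth a gene at 1 CPM has at least 15 counts per library, and counting error adds to the spread of genes below that level. Figures were drawn with matplotlib 3.10.9.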

Results

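The transcriptomes of sorted cancer cells and TME cells were compared between exercised and sedentary mice bearing Met1-iRFP tumours. Total counts were 15924340 to 25563245 in the 8 libraries of sedentary cancer cells and 20073700 to 25526059 in the 7 of exercised cancer cells. They were 16307545 to 35958441 in the 4 libraries of sedentary TME cells and 22682216 to 37388479 in the 4 of exercised TME cells. The series title names the immune microenvironment, features of the cancer cells and the interaction of both as the subjects of the study. The contrast of the sorted compartments comes first here because it gives the background of each cell type in either sort.

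Cancer cells and TME cells differed in 9201 of 17503 genes, with 4773 higher in cancer cells and 4428 lower by edgeR's quasi-likelihood test. TME cells held the markers of leukocytes, endothelium and fibroblasts. Clec10a, a lectin of macrophages and dendritic cells, differed by -5.31 ± 0.32 log2 (adjusted p = 6.32e-11). Its mean was 1.91 ± 0.773 CPM in sedentary cancer cells (n = 8) and 65.7 ± 16.5 in sedentary TME cells (n = 4). Tpsb2, a mast cell tryptase, differed by -5.67 ± 0.41 (adjusted p = 6.94e-10) and Cldn5, a tight junction protein of endothelium, by -5.29 ± 0.43 (adjusted p = 5.78e-10). The chemokine gene Ccl8, the endothelial receptor gene Robo4, the long noncoding RNA Meg3, Tmem51 and Snx20 had differences of -5.38 to -5.24. In cancer cells the 8 largest changes were Slco1a5, an organic anion transporter (2.23 ± 0.17, adjusted p = 4.37e-11), the EGF receptor ligand Btc (1.88 ± 0.18), Lancl3, the matrix protease Mmp10 (1.79 ± 0.16), Prrg4, the potassium channel gene Kcnf1, the NKG2D ligand Ulbp1 and the myosin Myo5b (1.54 ± 0.20).

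Of 65 gene lists, camera with the preset correlation called 5 higher in cancer cells and 32 higher in TME cells. MHC class II genes were lower in cancer cells, with a median of -4.25 log2 and 12 of 12 members past the gene-level threshold (12 adjusted over the list alone). Complement had a median of -3.43 with 13 of 16 members lower (13 adjusted over the list alone), and neutrophil genes -3.41 with 15 of 16 (15 adjusted over the list alone). These 3 lists alone kept their call with an estimated correlation, each at adjusted p = 0.0399. Macrophage genes had a median of -3.74 with 14 of 15 members lower (15 adjusted over the list alone; adjusted p = 0.0554 with an estimated correlation). Pan-leukocyte genes stood at -3.94 with 12 of 12 (12 adjusted over the list alone; adjusted p = 0.0591 with an estimated correlation). Endothelial genes stood at -3.76 with 13 of 14 (13 adjusted over the list alone; adjusted p = 0.0646 with an estimated correlation). Fibroblast genes stood at -2.89 with 12 of 15 lower and 1 higher (12 and 1 adjusted over the list alone; adjusted p = 0.0554 with an estimated correlation). Genes of G2 and M phase were higher in cancer cells, with a median of 0.62 and 18 of 24 members past the threshold (19 adjusted over the list alone; adjusted p = 0.282 with an estimated correlation), among them Anln at 1.09 ± 0.08 and Hmmr at 1.03 ± 0.11. Cholesterol synthesis had a median of 0.60 with 16 of 21 members higher and 2 lower (16 and 2 adjusted over the list alone; adjusted p = 0.368 with an estimated correlation), and S phase genes 0.33 with 16 of 25 higher and 2 lower (16 and 2 adjusted over the list alone; adjusted p = 0.361 with an estimated correlation).

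Abundant transcripts of the tumour were found in both sorts, so an exercise effect measured in the TME sort need not come from cells of the microenvironment. Spp1, which encodes osteopontin, had 15751 ± 2934 CPM in sedentary cancer cells (n = 8) and 12040 ± 1608 in sedentary TME cells (n = 4), and was higher in cancer cells by 0.33 ± 0.11 log2 (edgeR adjusted p = 0.0154). The epithelial secreted protein gene Wfdc2 had 333 ± 65.5 and 357 ± 74.4 CPM, and the keratin gene Krt18 had 93.2 ± 19.0 and 73.3 ± 19.9, in the same groups, and neither passed the threshold (-0.06 ± 0.12, adjusted p = 0.720, and 0.35 ± 0.15, adjusted p = 0.0526). Mitochondrial transcripts took 42.2% of the counts of sedentary TME library 4 and 14.5% of library 6, against 2.61% to 8.63% in the other TME libraries and 1.86% to 3.90% in cancer libraries. The 95% Wilson intervals of these shares are at most 0.0479 percentage points wide and cover counting error only. Without each of the 8 TME libraries more genes were lower than higher in cancer cells, from 3879 higher and 4796 lower without TME sedentary library 4 to 4400 and 4790 without TME sedentary library 9, so the side with more calls is not settled.

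**Figure D1:**
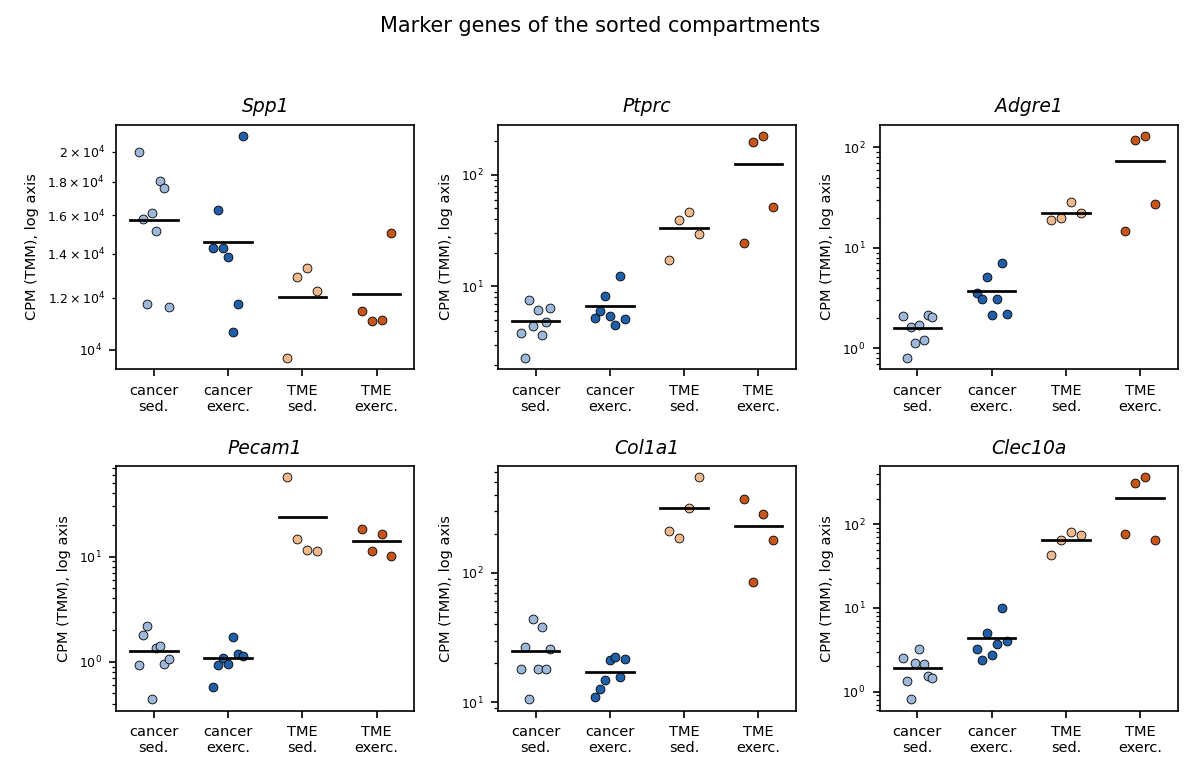
Normalised read counts (CPM after TMM scaling, log axis) of 6 marker genes in each of the 23 libraries, by compartment and treatment (sed., sedentary; exerc., exercised). Each point is a library and each bar the group mean; the exercised TME libraries 8 and 9 are the upper pair of points for Ptprc and Adgre1.

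Exercise in cancer cells moved no single gene past the threshold by edgeR, while DESeq2 called 161 and limma voom 196, and of the gene lists that of cell division had the smallest p. Hmmr, a spindle-associated receptor of hyaluronan, had 61.2 ± 7.97 CPM in sedentary (n = 8) and 86.8 ± 13.9 in exercised libraries (n = 7). This change of 0.48 ± 0.10 log2 missed the threshold (edgeR adjusted p = 0.0804) and lay above the sedentary mean in 7 of 7 libraries. Genes of G2 and M phase rose as a list (median 0.20, 21 of 24 members above 0, camera adjusted p = 1.51e-08). Heat shock genes (median -0.45, 12 of 13 below 0, adjusted p = 0.000158) and circadian clock genes (median -0.17, 12 of 18 below 0, adjusted p = 0.00294) fell. Lists of leukocyte markers were called higher too, with a pan-leukocyte median of 0.57 (adjusted p = 0.00331). None of these list calls held with an estimated correlation, as given for each list with its members.

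edgeR called 0 of 15096 genes, with 1901 genes at an unadjusted p under 0.05 (894 higher, 1007 lower; 755 would be expected if no gene changed and the p-values were uniform). DESeq2 called 161 and limma voom 196, of which 102 were shared. The number of calls was 28 without a filter, 174 with 1 surrogate variable, 43 without cancer sedentary library 4, 6 without cancer exercise library 10, 3 without cancer exercise library 5 and 1 without cancer sedentary library 3. Predicted genes were left out of the ranking, and 2 of them, 1110038B12Rik (-0.57 ± 0.10) and Gm42547 (-0.48 ± 0.09), had the smallest p of all. The 10 ranked genes all had adjusted p = 0.0804 and lay on the same side of the sedentary mean in 7 of 7 exercised libraries, which follows in part from ranking by p on these libraries. Those above 0 were Hmmr (chromosome 11, 40701395 to 40733422), the nucleolar protein gene Mybbp1a (chromosome 11, 72441355 to 72451768; 0.28 ± 0.06; 183 ± 9.58 to 225 ± 8.65 CPM), the nuclear pore gene Tpr (chromosome 1, 150392838 to 150449935; 0.36 ± 0.07), the dynein heavy chain gene Dync1h1 (chromosome 12, 110601452 to 110666945; 0.29 ± 0.06) and the fucosyltransferase gene Fut8 (chromosome 12, 77238125 to 77476338; 0.33 ± 0.07). Those below 0 were the death receptor gene Tnfrsf25 (chromosome 4, 152115934 to 152120119; -0.77 ± 0.15; 39.8 ± 9.02 to 23.6 ± 5.34 CPM), Nap1l2 (chromosome X, 103184176 to 103186640; -0.68 ± 0.13), Znrd1 (chromosome 17, 36954356 to 36958559; -0.45 ± 0.09), Rbm12b2 (chromosome 4, 12089439 to 12096243; -0.43 ± 0.09) and the GABA receptor gene Gabre (chromosome X, 72255999 to 72274803; -0.41 ± 0.08).

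Of the genes always reported in cancer cells, 21 were tested, and 0 passed over all genes while 4 passed adjusted over the list alone. These were the proliferation gene Mki67 (0.34 ± 0.09, adjusted p = 0.133 over all genes), the topoisomerase gene Top2a (0.38 ± 0.11, adjusted p = 0.166), the fatty acid synthase gene Fasn (0.33 ± 0.07, adjusted p = 0.0927; 873 ± 74.0 to 1108 ± 90.5 CPM) and Csf1, the growth factor of macrophages (-0.24 ± 0.08, adjusted p = 0.243). DESeq2 called Fasn (adjusted p = 0.00417), Mki67 (0.0384) and Top2a (0.0488). Over the alternatives the adjusted p ranged from 0.00417 to 0.999 for Fasn and from 0.0233 to 0.999 for Mki67. Cxcl10 stood at -0.49 ± 0.34, Cxcl9 at 0.29 ± 0.17, Ptgs2 at -0.26 ± 0.15, Slc2a1 at -0.17 ± 0.25, Ccnd1 at 0.17 ± 0.09, Ccl2 at 0.17 ± 0.23, Vegfa at -0.15 ± 0.20 and Epcam at -0.12 ± 0.31. Cd274, Vim, Cdkn1a, Ldha, B2m, Myc and H2-K1 lay between -0.07 and 0.10, and Krt8 had too few counts to be tested.

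In the G2 and M phase list 0 members passed over all genes, and 8 passed as higher and 1 as lower adjusted over the list alone (adjusted p = 0.709 with an estimated correlation). Hmmr, the kinetochore gene Cenpf (0.43 ± 0.11), Mki67 and Top2a had its smallest p-values. S phase genes were not called (median 0.05, adjusted p = 0.262). In the heat shock list, whose members are chaperones and their cofactors, 1 passed as lower adjusted over the list alone (adjusted p = 0.709 with an estimated correlation). The mitochondrial chaperonin gene Hspe1 had -0.45 ± 0.10, the small heat shock gene Hspb1 -0.75 ± 0.26, Bag3 -0.71 ± 0.26 and Hsph1 -0.69 ± 0.32. In the clock list 4 passed as lower adjusted over the list alone (adjusted p = 0.709 with an estimated correlation). They include the repressor gene Nr1d2 (-0.56 ± 0.11, adjusted p = 0.0804; 154 ± 17.7 to 106 ± 22.5 CPM), while Per3 had -0.45 ± 0.11, Dbp -1.06 ± 0.28 and Tef -0.50 ± 0.13. Cytosolic ribosomal protein genes fell by a median of -0.11, with 26 of 28 below 0 and 1 lower adjusted over the list alone (adjusted p = 0.00331; adjusted p = 0.714 with an estimated correlation). The exact permutation test of list levels gave p = 0.0266 for G2 and M phase, 0.0389 for the clock and 0.0803 for heat shock, each with an adjusted p of 0.274 to 0.344 over 60 lists.

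Lists of leukocyte markers were called higher in the exercised cancer sort with the preset correlation only. The monocyte list had a median of 0.35 (adjusted p = 0.0132; adjusted p = 0.393 with an estimated correlation) and T cell genes 0.53 (adjusted p = 0.0302; adjusted p = 0.709 with an estimated correlation). M2 macrophage genes had 0.28 (adjusted p = 0.0302; adjusted p = 0.709 with an estimated correlation; 2 higher adjusted over the list alone), macrophage genes 0.32 (adjusted p = 0.0371; adjusted p = 0.711 with an estimated correlation; 1 higher adjusted over the list alone) and mast cell genes 0.75 (adjusted p = 0.0371; adjusted p = 0.709 with an estimated correlation). The pan-leukocyte call had adjusted p = 0.709 with an estimated correlation. Cancer exercise library 8 had the highest pan-leukocyte level, 2.95 log2 CPM against 2.22 in the next library. Without it the pan-leukocyte (median 0.29, adjusted p = 0.0772), T cell (0.51), M2 macrophage (0.07), macrophage (0.11) and mast cell (0.45) lists lost their calls, while the monocyte list stayed (0.34, adjusted p = 0.0407). The T cell list also lost its call without cancer sedentary library 2 and exercise library 4, the M2 list without sedentary libraries 3 and 7 and exercise library 4, the macrophage list without sedentary libraries 3, 4 and 10 and exercise libraries 4 and 10, and the mast cell list without 10 libraries in all. Adgre1, which encodes the macrophage marker F4/80, had 1.60 ± 0.507 and 3.75 ± 1.74 CPM (1.22 ± 0.27, adjusted p = 0.0860), and Clec10a 1.91 ± 0.773 and 4.43 ± 2.62 CPM (1.21 ± 0.30, adjusted p = 0.128), far below their levels in TME cells. The pan-leukocyte level was 1.52 ± 0.288 in sedentary and 2.02 ± 0.474 log2 CPM in exercised libraries, with an exact permutation p = 0.0132 that missed the threshold after adjustment over 19 cell types (0.0837). Of the 19 cell type levels 0 passed by the exact permutation test, with 6 at an unadjusted p under 0.05. With the pan-leukocyte level as a covariate 6 lists were called, and 4 of the 18 remained, namely G2 and M phase, heat shock, clock and ribosomal proteins.

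The other 8 lists called in cancer cells were as follows. Adhesion and leukocyte trafficking (0.17, adjusted p = 0.0386) and interferon-gamma response (0.13, adjusted p = 0.0434) rose. Lysosome and autophagy (-0.10), exercise-responsive secreted factors (-0.18), nuclear-encoded oxidative phosphorylation (-0.11), collagen and extracellular matrix (-0.14), epithelial and mammary luminal genes (-0.32) and Hippo targets (-0.12) fell, at camera adjusted p-values of 0.0243 to 0.0371. Each of these 8 lists lost its call without at least 3 single libraries, the interferon-gamma list with a median of 0.04 without cancer exercise library 7, though 0.35 with its call kept without cancer sedentary library 10. Each lost it too, at adjusted p = 0.709 to 0.752 with an estimated correlation, and adjusted over the list alone 2 collagen and 2 luminal genes were lower. Among the secreted factors, the cytokine gene Il6 had -1.27 ± 0.42 (1.67 ± 0.823 to 0.700 ± 0.430 CPM, edgeR adjusted p = 0.235) and Cxcl1 -0.72 ± 0.35. Among the luminal genes Krt18 had -0.42 ± 0.13 and Wfdc2 -0.36 ± 0.12. In all, camera with the preset correlation called 18 of 60 lists, and with an estimated correlation and by fry 0, with 2 and 7 lists at an unadjusted p under 0.05. The count was 7 without cancer exercise library 8, 8 without cancer sedentary library 7, 9 without cancer exercise library 4 and 10 without cancer sedentary library 3. The 4 lists that kept their call without each library were G2 and M phase, heat shock, clock and monocyte, and the ribosomal list lost its call without cancer sedentary library 7 (-0.06). With the replicate number as a block 10 of the 18 kept their call, among them G2 and M phase, heat shock and clock. The monocyte (0.20, adjusted p = 0.172), pan-leukocyte (0.22, adjusted p = 0.244), T cell, macrophage, lysosome, collagen, adhesion and interferon-gamma lists lost their calls in that fit. It rests on numbers 2, 4, 5, 7 and 10 and gives cancer exercise library 8 no weight. These losses therefore cannot be told apart from the effect of using fewer libraries.

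**Figure D2:**
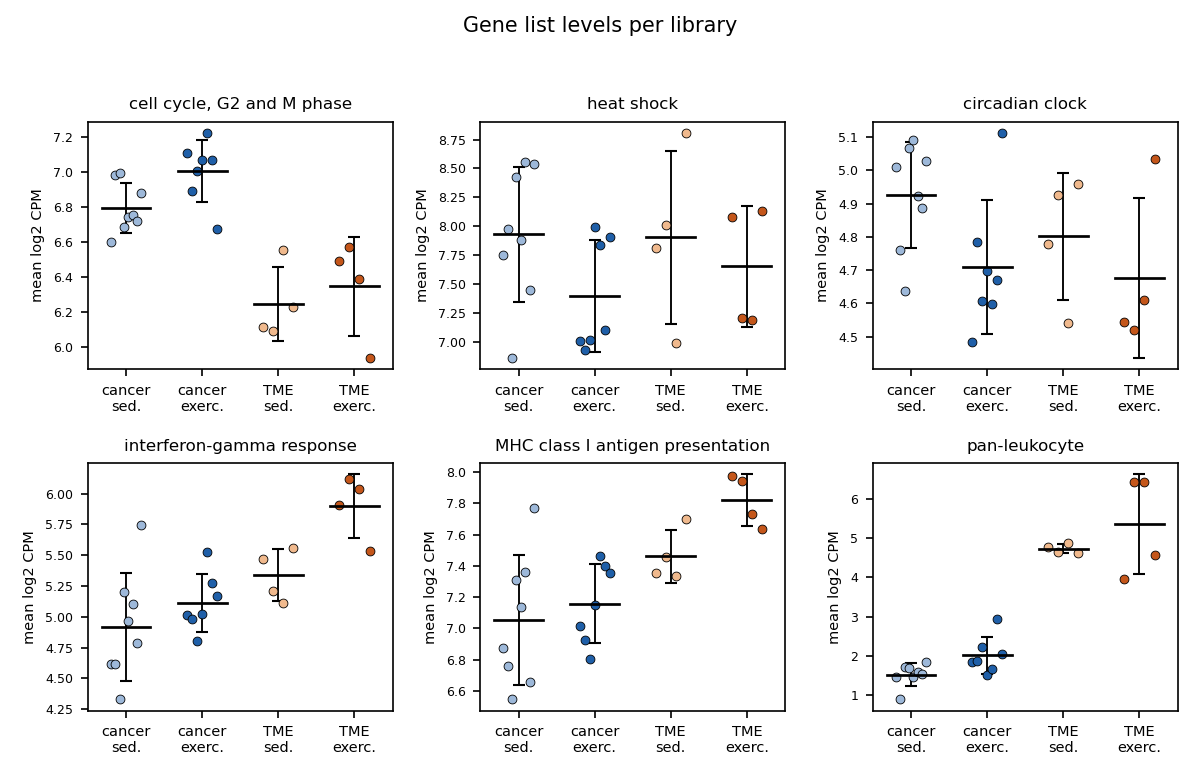
Mean log2 CPM of 6 gene lists in each of the 23 libraries, by compartment and treatment (sed., sedentary; exerc., exercised). Points are libraries, horizontal bars group means and vertical bars SD; in exercised TME cells the pan-leukocyte level is highest in libraries 8 and 9, while the level of the interferon-gamma list lies above the sedentary mean in 4 of 4 libraries.

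In TME cells edgeR called no single gene under exercise, while DESeq2 called 41 and limma voom 0, and of the gene lists that of the interferon-gamma response had the smallest p. Nlrc5, the transactivator of MHC class I genes, had 104 ± 19.3 CPM in sedentary and 183 ± 14.0 in exercised libraries (n = 4 each; 0.77 ± 0.14 log2), and the guanylate-binding protein gene Gbp5 had 30.7 ± 5.31 and 61.3 ± 15.9 (0.94 ± 0.18). Cd274, which encodes the checkpoint ligand PD-L1, had 26.0 ± 6.12 and 73.5 ± 34.9 CPM (1.43 ± 0.32). The interferon-gamma list rose with 22 of 22 members above 0 (median 0.47, camera adjusted p = 4.62e-13) and MHC class I genes with 15 of 17 (median 0.36, adjusted p = 3.52e-07), while endothelial genes fell with 13 of 14 below 0 (median -1.08, adjusted p = 2.92e-05; median -0.21 without TME sedentary library 4). The list calls were lost with an estimated correlation, each of these 3 at adjusted p = 0.515 with an estimated correlation. Tumour transcripts were found in the TME sort too, so these changes need not come from cells of the microenvironment.

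edgeR called 0 of 16273 genes (smallest adjusted p = 0.586), with 1373 at an unadjusted p under 0.05 (802 higher, 571 lower; 814 would be expected in the same way). DESeq2 called 41 (27 higher, 14 lower), limma voom 0 and the fit with no filter 6. The 10 ranked genes, with predicted genes left out, all had adjusted p = 0.586, lay on the same side of the sedentary mean in 4 of 4 exercised libraries, and were called by DESeq2 at adjusted p-values of 0.00856 to 0.0157. As they were ranked by p on these same libraries, this agreement is not separate evidence. Those above 0 were Nlrc5 (chromosome 8, 94434356 to 94527272), Gbp5 (chromosome 3, 142493978 to 142522344), the antiviral gene Rsad2 (chromosome 12, 26442746 to 26456452; 1.45 ± 0.28; 6.29 ± 0.775 to 17.9 ± 7.38 CPM), Gbp4 (chromosome 5, 105115767 to 105139586; 0.74 ± 0.15) and the MHC class I gene H2-Q6 (chromosome 17, 35424850 to 35430055; 1.02 ± 0.22). Those below 0 were Tnfrsf25 (-1.02 ± 0.20; 61.6 ± 10.1 to 31.3 ± 7.30 CPM), the nuclear receptor gene Nr2f1 (chromosome 13, 78188973 to 78199757; -0.68 ± 0.13), Agpat1 (chromosome 17, 34604262 to 34613449; -0.54 ± 0.11), Cplx2 (chromosome 13, 54371349 to 54383917; -0.89 ± 0.18) and the cytokine receptor gene Il20rb (chromosome 9, 100457719 to 100486788; -0.77 ± 0.16).

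Of the genes always reported in TME cells, 22 were tested, and 0 passed over all genes while 1, Cd274, passed adjusted over the list alone (0.0319; DESeq2 adjusted p = 0.00856, limma voom 0.143). Its adjusted p ranged from 0.00856 to 0.99988 over the alternatives. In the edgeR fit without the exercised TME libraries 8 and 9 no gene had an adjusted p below 0.99988. The leukocyte genes had large values with wide errors, as for Ptprc (1.82 ± 0.70), Cd4 (1.94 ± 0.57), Adgre1 (1.63 ± 0.67), Mrc1 (2.16 ± 0.84), Cd8a (1.51 ± 0.72), Gzmb (1.91 ± 1.02), Pdcd1 (1.19 ± 0.56), Ifng (1.28 ± 1.22), Arg1 (1.16 ± 0.73), Cxcl9 (0.90 ± 0.49), Cd3e (0.89 ± 0.83) and Foxp3 (0.90 ± 0.91). Without the exercised TME libraries 8 and 9 the sign turned for Adgre1 (-0.075), Mrc1 (-0.068), Cd8a (-0.24), Gzmb (-0.45), Ifng (-3.26), Arg1 (-0.60), Cxcl9 (-0.15), Cd3e (-0.93) and Foxp3 (-0.35). Ly6g, Prf1, Ly6c2, S100a8, Nos2, Flt3 and Epcam lay between -0.02 and 0.94, Col1a1 at -0.49 ± 0.53 and Pecam1 at -0.80 ± 0.59 (0.14 without TME sedentary library 4). Ncr1 had too few counts to be tested.

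Of the interferon-gamma list 9 members passed as higher adjusted over the list alone, against 0 over all genes, and of the MHC class I list 5, among them H2-Q7 (0.86 ± 0.20) and the peptide transporter gene Tap1 (0.58 ± 0.15). The type I interferon list had a median of 0.42 (adjusted p = 1.28e-05; 2 adjusted over the list alone; adjusted p = 0.515 with an estimated correlation), with Rsad2 and Oasl1 (1.13 ± 0.25). Macrophage genes had a median of 0.95 (adjusted p = 6.50e-07; 1 adjusted over the list alone; adjusted p = 0.515 with an estimated correlation), with Mertk, a receptor for apoptotic cells, at 0.93 ± 0.24. Mast cell genes had 1.37 (adjusted p = 1.64e-06), adhesion and leukocyte trafficking 1.21 (3.00e-06), complement 0.75 (3.79e-05), MHC class II 0.83 (3.79e-05), and M1 macrophage 0.58 (4.07e-05). Neutrophil genes had 0.87 (0.000192), monocyte 0.73 (0.000975), T cell checkpoint 1.19 (0.00105), M2 macrophage 1.07 (0.00161), CD4 and regulatory T cell 0.99 (0.00209), T cell 1.02 (0.00311), myeloid-attracting chemokines 1.26 (0.00311), NF-kB 0.22 (0.00386), pan-leukocyte 1.08 (0.00614), plasma cell 0.95 (0.0213) and matrix proteases 0.28 (0.0377). All of these lists lost their call, at adjusted p = 0.515 to 0.644 with an estimated correlation. Several medians rest in part on 1 library. Without TME exercise library 8 type I interferon had 0.20, MHC class II 0.46, CD4 and regulatory T cell 0.64, and plasma cell 0.50 with its call lost. Without TME exercise library 9 neutrophil had 0.57, monocyte 0.41, checkpoint 0.77 and myeloid-attracting chemokines 0.52, and without TME sedentary library 9 NF-kB had 0.08 with its call lost. NF-kB had 0.45 without TME sedentary library 10 and 0.46 without TME exercise library 8, with its call kept. Matrix proteases were not called without TME sedentary library 4 (0.27, camera adjusted p = 0.180). Adjusted over the list alone, complement had 2 higher members, and the mast cell, adhesion, neutrophil, checkpoint and NF-kB lists 1 each.

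Leukocyte content set the exercised TME libraries apart from each other. Ptprc, the common leukocyte antigen, had 196 and 223 CPM in libraries 8 and 9 and 17.3 to 51.3 in the other TME libraries. Without these 2 libraries 16 lists were called, and of the 20 lists that had risen 4 kept their call and direction, namely interferon-gamma (median 0.38), MHC class I (0.29), neutrophil and NF-kB. The macrophage median was then -0.22 and the pan-leukocyte median -0.46. With the pan-leukocyte level as a covariate 15 of the 20 kept their call, with 0.37 for interferon-gamma. Of 22 cell type levels 0 passed the exact permutation test and 0 had an unadjusted p under 0.05, with a smallest possible p of 0.0286, at which a single list could not pass the adjustment. The levels of the interferon-gamma and MHC class I lists were above the sedentary mean in 4 of 4 libraries, each with an exact permutation p = 0.0571 and adjusted p = 0.581 over 63 lists.

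Lists that fell in exercised TME cells were led by mitochondrially encoded transcripts (median -2.20, 13 of 13 below 0, adjusted p = 8.35e-06; adjusted p = 0.515 with an estimated correlation), where mt-Nd6 had -2.17 ± 0.88. Without TME sedentary library 4, which had the mitochondrial share of 42.2%, this median was -0.63 with the call kept (adjusted p = 0.00325). With the replicate number as a block it was 0.39 and called higher (adjusted p = 0.000258), in a fit that gives library 4 no weight. The same library had an endothelial level of 5.50 log2 CPM. Without it the endothelial median shrank from -1.08 to -0.21 (adjusted p = 0.0478), and with the replicate block it was -0.21 with the call lost (adjusted p = 0.134), so the size of this change rests on 1 library. Tie1, a receptor of endothelium, had -1.46 ± 0.61, from 20.2 ± 16.3 to 7.51 ± 3.75 CPM. Cytosolic ribosomal proteins (-0.16, adjusted p = 0.00147), nuclear-encoded oxidative phosphorylation (-0.10, 0.00162), collagen and extracellular matrix (-0.34, 0.00169), pericyte and smooth muscle (-0.58, 0.00310; 1 lower adjusted over the list alone), mammary basal genes (-0.43, 0.0351), Hippo targets (-0.20, 0.0377), Wnt signalling (-0.24, 0.0377) and heat shock (-0.44, 0.0499) also fell. Each lost its call, at adjusted p = 0.515 to 0.739 with an estimated correlation. Pdgfrb, the pericyte receptor of PDGF, had -0.57 ± 0.14. Without TME sedentary library 4 the pericyte list had -0.25 with its call kept (adjusted p = 0.0208) and the basal list -0.10 with its call lost (adjusted p = 0.0569). Calls were also lost without TME sedentary library 10 for collagen (-0.16), Hippo (-0.11), Wnt (-0.15) and heat shock (-0.03), without TME exercise library 8 for collagen (-0.18), Hippo (-0.12), Wnt (-0.09) and heat shock (-0.22), and without TME exercise library 10 for oxidative phosphorylation (-0.04). Of all lists called in TME cells 16 kept their call without each library, and 14 lost it without at least 1, among them ribosomal proteins without TME sedentary library 4 (-0.04), T cell genes without TME exercise library 8 (0.37), M2 macrophage genes without TME exercise library 9 (0.62) and pan-leukocyte genes without each of these 2. T cell genes had 1.93 with the call kept without TME sedentary library 9. With the replicate block 25 of the 30 kept call and direction, and the MHC class I (0.15, adjusted p = 0.167), endothelial, pericyte and T cell lists lost their calls. That fit rests on numbers 9 and 10 alone, so it does not test all 8 TME libraries. In all, camera with the preset correlation called 30 of 63 lists, and with an estimated correlation and by fry 0, with 2 and 4 lists at an unadjusted p under 0.05. The clock list, which fell in cancer cells, had a median of -0.07 (adjusted p = 0.145) and G2 and M phase 0.12 (adjusted p = 0.324).

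**Figure D3:**
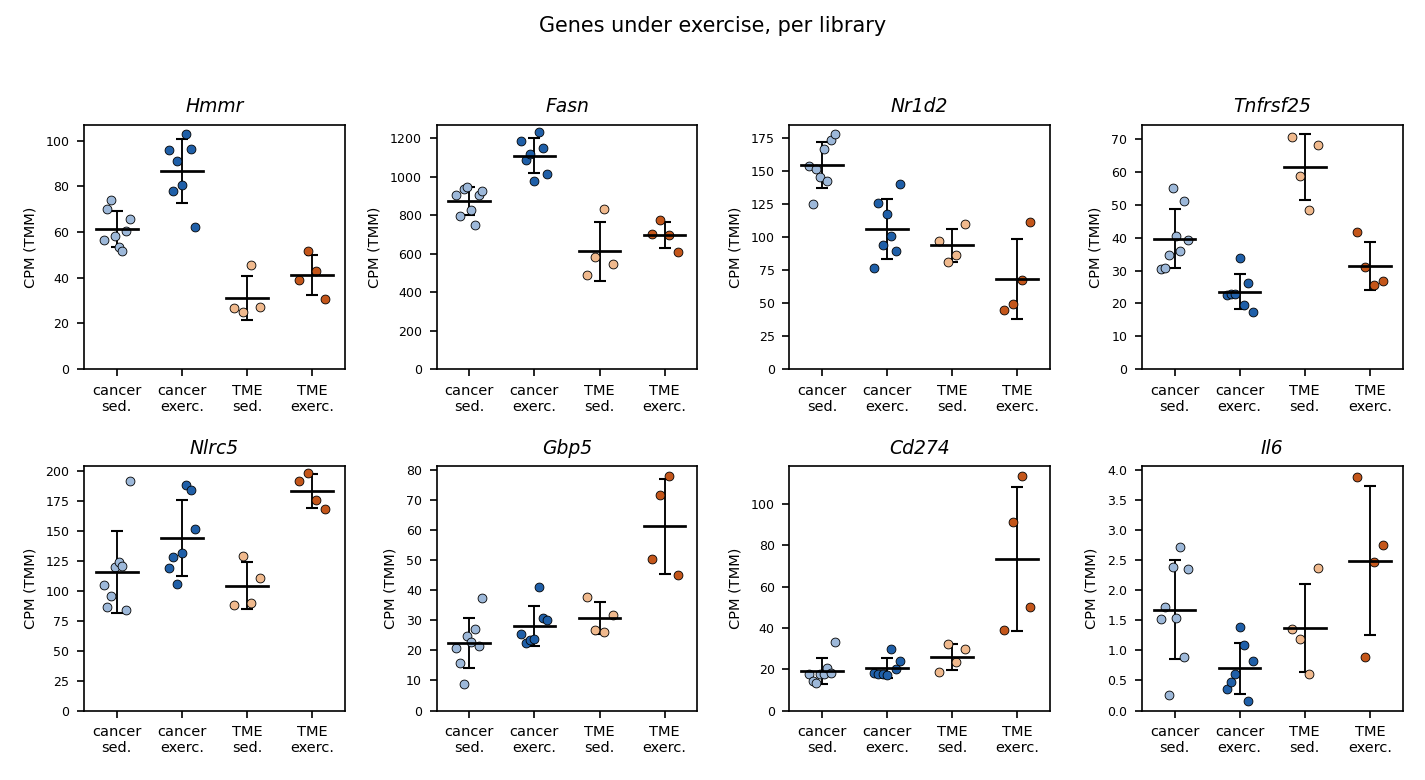
Normalised read counts (CPM after TMM scaling, linear axes from 0) of 8 genes in each of the 23 libraries, by compartment and treatment (sed., sedentary; exerc., exercised). Points are libraries, horizontal bars group means and vertical bars SD; Tnfrsf25 has means of 39.8 and 23.6 CPM in cancer cells and 61.6 and 31.3 in TME cells, and no gene shown passed the edgeR threshold under exercise.

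The exercise effect was compared between compartments to ask whether cancer and TME cells responded differently. The values nearest to the threshold were those of Ank3, a membrane scaffold gene (TME minus cancer effect -0.72 ± 0.14, edgeR adjusted p = 0.237), and of Helz (-0.53 ± 0.11, adjusted p = 0.358). Ank3 had 56.6 ± 6.37 and 68.8 ± 6.21 CPM in sedentary and exercised cancer cells and 67.3 ± 4.57 and 51.2 ± 7.35 in TME cells. The lysosomal peptidase gene Dpp7 (1.25 ± 0.30), Bst1 (1.23 ± 0.28), Lonrf1 (1.42 ± 0.36), Sowahc (0.75 ± 0.20) and Lacc1 (0.81 ± 0.21) had the smallest p above 0, and Cplx2 (-0.88 ± 0.20), Lmod1 (-1.02 ± 0.24) and the myosin gene Myh10 (-0.47 ± 0.11) were next below 0, all at adjusted p = 0.464. edgeR called 0 of 17503 genes, with 1316 at an unadjusted p under 0.05, while DESeq2 called 2, limma voom 36 and edgeR with the replicate number as a block 14 (smallest adjusted p = 0.00519). Without TME exercise library 7 the count was 52.

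Both effects shared part of their direction across genes. Abundant tumour transcripts such as Spp1, Wfdc2 and Krt18 were found in both sorts. The correlation therefore does not show that distinct cell types responded alike. Over 14775 genes the log2 fold changes of cancer and TME cells had r = 0.301 and rho = 0.278, with the same sign in 60.2%. Genes are not independent replicates, and treatment labels permuted within each compartment gave r from -0.352 to 0.211 (permutation p = 0.0198 for r and for rho). That permutation parts sorts that may share a tumour. Labels were also moved together for both sorts of the same number and treatment. This gave r from -0.139 to 0.275 (permutation p = 0.0099 for r and for rho), and it rests on reading the numbers as tumours. Among 10246 genes with a mean CPM of at least 5, r was 0.343 (permutation p = 0.0297) and rho 0.324 (permutation p = 0.0891), and the highest permuted r was 0.365, above the observed one. With the pan-leukocyte level as a covariate in both fits r was 0.103 (permutation p = 0.139).

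Ligand and receptor pairs address the interaction of both compartments. In 114 tested combinations of a ligand in one compartment with its receptor in the other, 0 had both genes past the threshold by edgeR. Adjusted over the pair genes alone, 0 of 108 genes passed in cancer cells (smallest adjusted p = 0.268, Csf1; 16 at an unadjusted p under 0.05) and 0 of 126 in TME cells (0.0912, Cd274; 27). The monocyte chemokine gene Ccl2 in TME cells (1.66 ± 0.67) and its receptor Ccr2 in the cancer sort (0.87 ± 0.33) had the smallest larger p of a pair. They were followed by Ccl7 with Ccr2, by Csf1 in cancer cells (-0.24 ± 0.08) with Csf1r in TME cells (1.52 ± 0.68), by Cxcl1 with Cxcr2, and by Apoe in TME cells with Lrp1. Leukocyte markers were found in the cancer sort too, so a receptor gene measured there need not be expressed by cancer cells.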

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

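The tests of gene length and GC content, of the leukocyte covariate in TME cells, of removal of TME libraries 8 and 9, of the clock output genes, of the pan-leukocyte and endothelial levels against each other and of other splits of the libraries were chosen after the results were seen, as were the gene lists in the difference between compartments, while the leukocyte covariate in cancer cells and leaving out each library were planned and the conditions set on them were written after the results were seen.

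Cell cycle genes rose and heat shock and ribosomal protein genes fell in exercised cancer cells, as lists (adjusted p = 0.709, 0.709 and 0.714 with an estimated correlation). With length and GC correction the medians were 0.16, -0.42 and -0.077, and with the pan-leukocyte level as a covariate 0.24, -0.41 and -0.14. The cell cycle and heat shock lists kept their calls both times, which argues against either trend as the whole source. Other technical sources were not tested for these lists. Immediate early genes were not called, but 16 of 18 members lay below 0 as well (median -0.21, camera adjusted p = 0.0746). The ribosomal list kept its call with the covariate (adjusted p = 0.0410) and lost it with the length and GC correction (adjusted p = 0.0687), where the median shrank from -0.11, so a length or GC trend could explain part of it. A grouping by chance stays open for all 3 lists, since 16 of 60 splits of the cancer libraries called as many lists as the real 18 (highest other 26), and an effect of exercise on division is a hypothesis beside it.

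Immune lists rose in exercised TME cells with the preset correlation, and each lost its call (adjusted p = 0.515 to 0.644 with an estimated correlation). Without TME sedentary library 4, with its high mitochondrial share, 27 of the 30 called lists and 19 of the 20 that rose kept call and direction, which argues against that library as the source. Without the exercised TME libraries 8 and 9, 4 of the 20 lists that rose kept theirs, so most of the pattern may rest on these leukocyte-rich libraries, though they were picked by their leukocyte level, which makes this test partly circular. The interferon-gamma and MHC class I lists, singled out because they held without those libraries, had medians of 0.37 and 0.34 with the pan-leukocyte level as a covariate and kept their calls, which argues against the pan-leukocyte level as their whole source, but 15 of the 20 lists kept theirs, macrophage with 0.14 (0.95 before) and neutrophil with 0.40 (0.87 before), so the content of single leukocyte types stays open. With the replicate block, which rests on numbers 9 and 10, the MHC class I list lost its call (0.15, camera adjusted p = 0.167). A lower share of cancer cells in the exercised sort stays open, with a difference of 1.40 ± 1.02 (SE) between the changes of the pan-leukocyte and endothelial levels. Against the fibroblast and pericyte levels it was 0.66 ± 0.75 and 0.93 ± 0.76 (SE). The endothelial level was 5.50 log2 CPM in TME sedentary library 4 and 3.63 in the nearest library of its group, so the first difference rests in part on 1 library. Of 35 splits, 6 called at least the real 30 lists (highest other 35), so chance was not excluded.

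Clock genes fell in exercised cancer cells as a list (adjusted p = 0.709 with an estimated correlation), with medians of -0.28 to -0.11 and the call kept without each library, -0.28 without cancer exercise library 10. With the pan-leukocyte level as a covariate the median was -0.15 and the call was kept, which argues against leukocyte RNA as the source. The output genes Dbp, Tef, Nr1d1, Nr1d2 and Per3 were singled out after their values in cancer cells were seen, where their mean change of -0.65 log2 is descriptive only. In TME cells it was -0.67 ± 0.28 (SE; exact permutation p = 0.0857; n = 4 each). A different time of day at collection may shift both compartments alike and goes with this value. It cannot be told apart from an effect of exercise on the clock, because the labels give no time of collection. Tumour transcripts were found in the TME sort too, so the value in TME cells need not come from cells of the microenvironment.

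Counts of called genes were set against other splits of the libraries. A real count of 0 is reached by any split, so 60 of 60 in cancer cells (highest other 12; DESeq2 161, limma voom 196 in the real split), 35 of 35 in TME cells (highest other 6; DESeq2 41, limma voom 0) and 60 of 60 in the difference between compartments (highest other 989; DESeq2 2, limma voom 36) were fixed and say nothing of chance. Genes at an unadjusted p under 0.05 were counted as well. In cancer cells 2 of 60 splits reached the real 1901, a share under 0.05, and the other of these (2116) was the real split with cancer sedentary library 3 and cancer exercise library 10 exchanged, which keeps most of the real contrast. In TME cells 8 of 35 splits reached the real 1373 (highest other 3708, with TME sedentary library 9 and TME exercise library 7 exchanged), and in the difference 22 of 60 reached the real 1316 (highest other 4059), so chance was not excluded in either. The splits of the difference with 989 and 4059 genes parted the TME libraries as that with 3708 did. They use the same TME libraries, so this is not separate evidence. TME sedentary library 9 and TME exercise libraries 8, 9 and 10 stood on the same side. Ptprc had 46.5 to 223 CPM in these libraries and 17.3 to 39.2 CPM in the other TME libraries. The parting thus goes with leukocyte content, whose part in these counts was not tested. Chance was excluded for cancer against TME cells, where 1 of 60 splits, the real one, reached 9201 genes (highest other 2127). By limma voom 2 of 60 splits reached the real count of 196 in cancer cells, a share under 0.05, and the highest other, 645, came from the same split with libraries 3 and 10 exchanged.

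The exercise effect differed between compartments in 16 of 65 lists by camera with the preset correlation on the difference itself. Each of the 16 lost its call, at adjusted p = 0.713 to 0.798 with an estimated correlation, and with the replicate block none of them was called, while 1 other list was (collagen, -0.32, adjusted p = 0.0316). The TME minus cancer medians above 0 were 0.71 for macrophage, 0.92 for adhesion and leukocyte trafficking, 0.39 for interferon-gamma, 0.52 for NF-kB, 0.58 for M1 macrophage, 0.78 for T cell checkpoint, 0.17 for lysosome, 0.40 for type I interferon, 0.59 for MHC class II, 0.25 for MHC class I, 0.34 for matrix proteases and 0.79 for myeloid-attracting chemokines. Those below 0 were -2.20 for mitochondrially encoded transcripts, -0.19 for MYC targets, -0.080 for G2 and M phase and -0.41 for mammary basal genes. No member passed over all genes, and adjusted over the list alone 10 mitochondrial genes were lower, and 5 macrophage, 2 MHC class II, 1 interferon-gamma and 1 checkpoint genes were higher. The mitochondrial median rests on TME sedentary library 4, and was -0.63 without it (adjusted p = 0.0177) and -0.87 with the replicate block (adjusted p = 0.403). Without TME sedentary library 9, and without TME exercise library 9, 6 lists were called, with 5 and 6 of the 16 among them, and 26 of 60 splits called at least 16 (highest other 38), so chance was not excluded.

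A single library stood apart from its group in 17 of 228 groups of values, where 11.4 would be expected by chance. Cancer sedentary library 7 had a mitochondrial share of 3.90% (nearest library 3.20%), a TMM factor of 0.984 (1.01) and a Vim level of 12.14 log2 CPM (11.71). Cancer sedentary library 3 had a pan-leukocyte level of 0.90 log2 CPM (1.46) and a macrophage level of 3.09 (3.59). Cancer sedentary library 4 had an endothelial level of 1.08 (1.76) and a Cxcl10 level of 2.01 (3.66), and cancer sedentary library 10 a Cd274 level of 5.06 (4.37). Cancer exercise library 10 had a TMM factor of 0.963 (1.01) and a Myc level of 6.94 (6.44), cancer exercise library 5 a Dync1h1 level of 9.62 (9.73), and cancer exercise library 1 an endothelial level of 1.22 (1.54). TME sedentary library 4 had an endothelial level of 5.50 (3.63) and a Pecam1 level of 5.83 (3.90), TME sedentary library 9 a Gbp4 level of 5.95 (6.44), TME exercise library 8 a Ly6g level of -1.68 (-0.34) and TME exercise library 10 a Schwann cell level of 2.61 (2.28).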

How the results depend on the processing

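Length and GC correction, removal of the exercised TME libraries 8 and 9, the leukocyte covariate in TME cells and in the correlation, the exact permutation of levels beyond the cell type lists and the lists in the difference between compartments were tests chosen after the results were seen. The cause of a change was not tested unless stated.

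In cancer cells edgeR called 0 genes with RLE factors, a mean CPM of at least 1, the replicate block and the leukocyte covariate (1901 at an unadjusted p under 0.05 in the fit reported). DESeq2 called 161, limma voom 196, the fit with no filter 28, that of all 23 libraries 1, 1 surrogate variable 174, and length and GC correction 1. Leaving out each library gave 0 to 43, with 43 without cancer sedentary library 4, 6 without cancer exercise library 10, 3 without cancer exercise library 5 and 1 without cancer sedentary library 3. In TME cells DESeq2 called 41, the fit with no filter 6 and limma voom 0, and leaving out each library gave 0. In the difference DESeq2 called 2, limma voom 36 and the replicate block 14, and leaving out each library gave 0 to 52, with 52 without TME exercise library 7. Cancer against TME cells gave 7360 to 9738 genes over the alternatives and 8599 to 9427 without each library. With RLE factors 4193 were higher and 4905 lower in cancer cells, with DESeq2 4348 and 4980, with no filter 4701 and 5037, with a mean CPM of at least 1 3886 and 4185, and more were lower without each of the 8 TME libraries, so which side has more calls is not settled.

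Of the 18 lists called in cancer cells, 4 kept their call with the leukocyte covariate, which called 6 in all. An estimated correlation, fry and the exact permutation of list levels gave 0 each (10 lists at an unadjusted exact p under 0.05). Leaving out each library gave 7 to 21, with 6 to 18 of the 18 among them. Of the 30 in TME cells, 8 kept call and direction on removal of libraries 8 and 9, which called 16 in all. An estimated correlation, fry and the exact permutation gave 0 each (0 lists at an unadjusted exact p under 0.05). The smallest possible exact permutation p was 0.0286, so the adjusted test could pass only if many lists reached it at once, and its 0 says little. Leaving out each library gave 24 to 36, with 22 to 29 of the 30 among them. Of the 16 in the difference 0 were called with the replicate block, which called 1 other list, and 0 with an estimated correlation and with fry. The 37 in cancer against TME cells became 3 with an estimated correlation, and were 36 to 38 without each library, while fry called 51 with all 37 among them. The correlation of both exercise effects was 0.103 with the leukocyte covariate and 0.343 over genes with a mean CPM of at least 5.

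With the leukocyte covariate in cancer cells the medians were -0.14 for the pan-leukocyte, 0.0078 for the macrophage (whose test turned) and -0.024 for the adhesion list, and in TME cells -0.017 for the pan-leukocyte list. The covariate is built from leukocyte genes, so this follows from its construction. With the replicate block in TME cells, which rests on numbers 9 and 10, mitochondrially encoded transcripts had 0.39 and were called higher, and MHC class I genes had 0.15 without a call. Without libraries 8 and 9 the medians were -0.46 for pan-leukocyte, -0.22 for macrophage, -0.091 for type I interferon, -0.15 for MHC class II, 0.025 for monocyte (whose test turned), -0.16 for checkpoint, -0.11 for M2 macrophage, -0.44 for T cell and 0.032 for heat shock.

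In cancer cells H2-K1 was 0.013 with 1 surrogate variable, B2m -0.078 with the replicate block and -0.11 with the leukocyte covariate, and Ccl2 -0.15 with that covariate. In TME cells 1 surrogate variable gave Cd3e -1.01, Cd8a -0.21, Foxp3 -0.57, Gzmb -0.33, Prf1 -1.51, Ifng -2.62, Adgre1 -0.069, Mrc1 -0.023, Arg1 -0.57, Ly6c2 -0.28 and Flt3 -1.30. The leukocyte covariate gave Cd3e -0.53, Foxp3 -0.27, Prf1 -1.13, Ifng -1.80, Arg1 -0.10, Ly6c2 -0.011 and Flt3 -0.84. Removal of libraries 8 and 9 gave Cd3e -0.93, Cd8a -0.24, Foxp3 -0.35, Gzmb -0.45, Prf1 -1.37, Ifng -3.26, Adgre1 -0.075, Mrc1 -0.068, Arg1 -0.60, Ly6c2 -0.42, Flt3 -1.59 and Cxcl9 -0.15. The replicate block gave Ifng -0.73, Flt3 -0.50, Pecam1 0.14 and Epcam 1.24, and Epcam was 0.98 with limma voom, 0.079 with the epithelial covariate and 0.013 with length and GC correction.

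Without each library the ranges that cross 0 in cancer cells were -0.15 to 0.021 for Myc (sedentary 7), -0.23 to 0.0028 for Cdkn1a (exercise 4), -0.30 to 0.027 for Epcam (sedentary 5 and 6, exercise 4), -0.0063 to 0.16 for Vim (exercise 10), -0.011 to 0.26 for Cd274 (exercise 7), -0.12 to 0.086 for H2-K1 (sedentary 7 and 10, exercise 2 and 4). The range was -0.0060 to 0.13 for B2m (sedentary 3 and 4). The libraries that turned each sign are in brackets. In TME cells the ranges were -0.16 to 1.11 for Prf1 (exercise 8), -0.14 to 0.61 for Flt3 (exercise 8 and 9), -1.04 to 0.14 for Pecam1 (sedentary 4) and -0.42 to 0.44 for Epcam (sedentary 4 and 6, exercise 7 and 10). Over the other alternatives 241 values of named genes in cancer cells and 325 in TME cells kept direction and side of the threshold, and 45 and 17 gained a call. At about 1.3 CPM, the depth limits what can be said of Epcam.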

Other observations

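The test of Tnfrsf25 and the mean of both exercise effects were chosen after the gene had been seen in both compartments, while the conditions for the splits of that mean and for the shared leukocyte level were written before those results.

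Tnfrsf25, singled out after its values were seen, had a mean effect over both compartments of -0.87 ± 0.13 log2, with an adjusted p of 0.00509 by limma voom with the tumour as a correlated block. The hypothesis that exercise lowers Tnfrsf25 stays open, since the gene was found and tested on the same libraries. Tumour transcripts were found in both sorts, so the fall of Tnfrsf25 in both is not evidence from distinct cell types. In this mean edgeR called 82 of 17503 genes (60 higher, 22 lower), and 3 of 60 splits reached that count (highest other 874, which points to a structure of the samples), so chance was not excluded. With the tumour block 3 genes were called, Tnfrsf25, Il20rb (-0.60 ± 0.10, adjusted p = 0.0263) and Gm15501 (-1.18 ± 0.21, adjusted p = 0.0418), named after their values were seen.

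The number in a library's name may mark a tumour shared by both sorts. Over the 7 numbers with both sorts in a treatment, the deviations of the pan-leukocyte level had Pearson r = 0.864 (exact permutation p = 0.0204) and Spearman rho = 0.536 (exact permutation p = 0.236), and r was 0.148 without the 2 farthest libraries, so the relation rests on these. Across 11928 genes, 4 of 7 such pairs had a correlation of residuals over 0.1 (-0.204 to 0.383), where genes are not independent replicates. Whether the numbers mark tumours stays open. The comparisons between groups did not pair libraries by number, while the tumour block above takes each number in a treatment as 1 tumour (16 tumours, 7 with both sorts, consensus correlation 0.0693), so the adjusted p of 0.00509 for Tnfrsf25 depends on that reading.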
